A study of Mus musculus with 16 samples.

How the data were processed

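Libraries came from medulloblastomas of SmoM2-overexpressing and Sufu;Spop double knockout (DKO) mice at postnatal day 13. Per the labels' protocols, tumours were crosslinked with formaldehyde and sonicated, chromatin was immunoprecipitated with a Gli2, H3K27ac or H3K36me3 antibody, and part of the lysate was kept as input. The same protocol text also names an Olig2 antibody bound to the beads, which no sample label lists, so which antibody was on the beads is not clear from it, and Gli2 lists are named here by the antibody given for each sample. Samples were grouped by the genotype and antibody in the labels, which gives 8 groups of 2 libraries, 4 of the 16 libraries being input. Per the labels, both libraries of a genotype and antibody share 1 deposited peak list. Whether reads were pooled before peak calling or peaks were merged afterwards, and whether the input served as the control, is not given in the sources used here. The labels do not say whether the 2 libraries came from separate animals.

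Per the submitters' processing notes, Trimmomatic 0.36, BWA, bedtools and MACS2 were used with build mm9. The roles of these tools, the versions of all but Trimmomatic and the calling settings are not given in the sources used here. Gli2 peaks were deposited in the narrow peak format and histone regions in the broad peak format, with no header. Other columns the authors deposited hold the start, end and, for Gli2, summit position of each region. The authors' fold enrichment is a ratio over the caller's background. The authors' p and q values are given as −log10. The deposited score is 10 times −log10 q as a whole number, up to rounding. These values were used only to describe, rank or filter peaks within a list, except in the tests of technical explanations, where fragment numbers recovered from them were compared. The lists state no read numbers, so the depth of each library is unknown.

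Peaks on chromosomes 1 to 19, X and Y were used, which left out 1 SmoM2 Gli2 peak on the mitochondrial sequence. No region ran past the end of its mm9 chromosome. Regions were counted as overlapping when they shared at least 1 base. Shares were given Wilson 95% intervals, and differences of shares Newcombe intervals. Chance overlap was described by placing regions at random on their own chromosome, 1000 times for Gli2 peaks and 100 times for histone regions, without excluding assembly gaps, so chance overlap outside gaps is somewhat understated. Classes of Gli2 peaks were compared within a list by 2-sided permutation tests of the difference in medians with 100000 resamples. Coverage was summed in stretches of 1 Mb. Chromosome lengths came from the mm9 table of the Bioconductor package GenomeInfoDb. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

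No annotation of build mm9 was used. The gene table at hand is of another assembly (GRCm38.p6), none of its coordinates were used and none were converted, so genes, exons and introns at the reported positions are not analysed here, nor are the lists of Hedgehog targets and cell type markers fixed for that purpose. By the rule fixed before the data were examined, positions stand in for genes: the 10 Gli2 peaks with the highest −log10 q in each genotype, the 10 widest H3K27ac regions in each genotype after joining regions at most 10 kb apart, and the 5 stretches of 1 Mb with the largest difference in each direction for each histone mark. A few of each are given in full. The tests of the comparisons, the planned settings and this rule were fixed before the data were examined. The comparison of chromosomes, the clusters of Gli2 peaks, 3 added alternatives and the tests of technical explanations were added afterwards, those of sequencing depth, chromatin quality and local background once their results had been seen.

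For the tests of technical explanations, the number of fragments at each Gli2 summit and the local background were recovered from the deposited fold and −log10 p, taking fold as (fragments + 1) divided by (background + 1) and p as the upper tail of a Poisson distribution. Whole fragment numbers solved both values within 0.01 of −log10 p for all 149 SmoM2 and 1426 DKO peaks. The lowest background was shared by many peaks and is called the floor. It was 1.40 fragments in the SmoM2 list (48 peaks) and 1.30 in the DKO list (760 peaks). On simulated data, 200 of 200 planted overlaps and 499 of 499 simulated fragment numbers were recovered. The simulated backgrounds were low. Recovery was not simulated at the high backgrounds of some peaks, up to 205 fragments in the SmoM2 and 152 in the DKO list.

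The alternatives included stricter thresholds (−log10 q of at least 5 or 10, fold of at least 5 for Gli2 and 3 for histone regions). Further ones were other definitions of overlap, joining of regions at most 1 or 10 kb apart, lists of equal length and all sequences. For the chance overlap of Gli2 peaks, they were also placed at random within the combined H3K27ac regions of both genotypes, without bridging gaps. Those added after seeing the data left out chromosomes X and Y, kept only Gli2 peaks with a local background at most 1.5 times the floor, or, only for clusters and for the widest H3K27ac regions, placed Gli2 peaks within the joined H3K27ac regions of their own genotype.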

Results

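Gli2 binding and the histone marks H3K27ac and H3K36me3 were profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in medulloblastomas of mice at postnatal day 13. Tumours of 2 genotypes were compared. In the first, tumours overexpressed SmoM2, a constitutively active form of the Hedgehog receptor component Smoothened. In the second, both Sufu and Spop were knocked out (double knockout, DKO). Sufu binds Gli proteins and restrains them, and Spop is the adaptor through which the Cul3 ubiquitin ligase recognises Gli proteins. Gli2 is a transcriptional activator of the Hedgehog pathway, H3K27ac marks active promoters and enhancers, and H3K36me3 marks the bodies of transcribed genes. The series held 16 libraries, with 2 for each antibody and 2 of input DNA in each genotype. The 12 ChIP libraries were represented by 6 peak lists, 1 per genotype and antibody, each standing for 2 libraries. No difference between genotypes therefore has a replicate check, and the read depth behind the lists is unknown. Positions are given in mouse build mm9. Intervals are Wilson 95% intervals and cover counting error only.

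Gli2 occupied many more called sites in DKO tumours than in SmoM2 tumours. The DKO list held 1426 Gli2 peaks and the SmoM2 list 148 on the same chromosomes, a ratio of 9.64. DKO peaks had a median width of 165 bp and SmoM2 peaks of 138 bp. More than 1 in every 2 SmoM2 peaks lay at a site also called in DKO tumours (85 of 148, 57.4%, 49.4–65.1%), whereas 5.96% (4.85–7.31%) of DKO peaks overlapped a SmoM2 peak. SmoM2 peaks placed at random on their own chromosomes overlapped DKO peaks in 0.027% of cases on average, and at most 2 peaks did so in any of 1000 placements. When placed within H3K27ac regions, 1.76% did so on average and at most 4.73%. With the 148 highest DKO peaks in place of the whole DKO list, 44 SmoM2 peaks overlapped (29.7% of each list), and among peaks with −log10 q of at least 10 the ratio of peak numbers was 15.4.

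The site with the highest −log10 q was the same in both genotypes, on chromosome 1 at 157059649–157059879 in SmoM2 and 157059613–157059967 in DKO tumours. It overlapped an H3K27ac region in both. The authors' fold enrichment there was 25.2 in the SmoM2 list and 87.4 in the DKO list, and each such value is the peak's own and ranks it only within its list. Among the 10 DKO peaks with the highest −log10 q, 9 were also called in SmoM2 tumours, 9 overlapped H3K27ac of SmoM2 tumours and 9 overlapped H3K27ac of DKO tumours. They included chromosome 7 at 133152214–133152733 (fold enrichment 57.4), chromosome 5 at 115618679–115618957 (51.3) and chromosome 13 at 112788581–112789131 (42.0), each with H3K27ac in both genotypes. The DKO peak on chromosome 9 at 72951182–72951858 (52.6) overlapped H3K27ac in DKO tumours only, and that on chromosome 15 at 64410578–64410937 (45.5) in SmoM2 tumours only. The peak on chromosome 11 at 119383795–119384470 (43.1) was the only one of these 10 absent from the SmoM2 list.

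The 10 highest SmoM2 peaks were more mixed. Of these, 5 were called in DKO tumours, 4 overlapped H3K27ac of SmoM2 tumours and 5 overlapped H3K27ac of DKO tumours. The peak on chromosome 14 at 54763634–54763840 (fold enrichment 14.4) was in both lists and in H3K27ac of both genotypes. The peak on chromosome 6 at 51542366–51542505 (17.1) lay in H3K27ac of both genotypes but was not called for Gli2 in DKO tumours. The peaks on chromosome 1 at 122837252–122837374 (16.7), chromosome 3 at 67514928–67515056 (15.2) and chromosome 9 at 103497639–103497773 (15.0) were called in SmoM2 tumours only and overlapped no H3K27ac region of either genotype. The peak ranked second, on chromosome 11 at 53953566–53953790, had a fold enrichment of only 2.58. It had the highest recovered local background of its list, with 531 fragments over 205 against a floor of 1.40. The DKO peak there (fold enrichment 2.26) likewise had the highest background of its list, with 344 fragments over 152.

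Sites called in both genotypes ranked high within the DKO list. Their median fold enrichment was 18.7 (n = 85), compared with 9.13 for the 1341 peaks found in DKO tumours only, and their median width was 259 bp compared with 162 bp. The 2-sided permutation p over peaks was 2e-05 for both, which is the smallest these permutations can give. Within the SmoM2 list the contrast was smaller, with a median fold enrichment of 7.20 for the 85 peaks in both lists and 5.67 for the 63 peaks in SmoM2 tumours only (permutation p = 0.0004). With the DKO peaks divided by −log10 q into 10 equal parts, 44 of 143 in the highest part (30.8%, 23.8–38.8%) were in the SmoM2 list. The share was 12.7% (8.17–19.1%) in the next part and between 0 and 4.90% in the other 8. These p-values describe the peaks of a list, not the variation between animals.

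**Figure D1:**
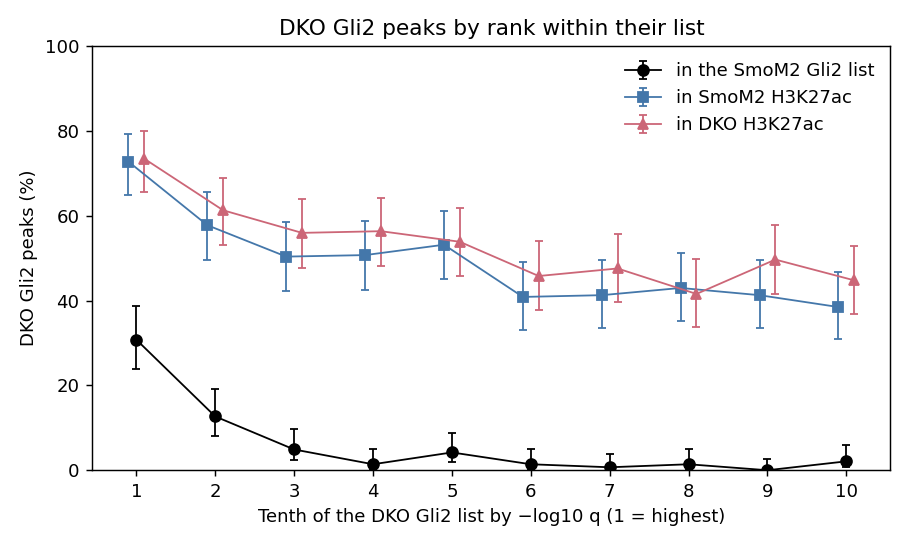
DKO Gli2 peaks divided into 10 equal parts by −log10 q (horizontal axis, 1 = highest) and the percentage of each part that overlaps a SmoM2 Gli2 peak (circles), an H3K27ac region of SmoM2 tumours (squares) or of DKO tumours (triangles), with Wilson 95% intervals as bars. The share in the SmoM2 Gli2 list falls from 30.8% in the first part to 4.90% or less from the third part on, while the share in DKO H3K27ac falls from 73.4% to between 41.5% and 56.3%.

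To ask whether sites called in 1 genotype carried the active mark there, Gli2 peaks were set against the H3K27ac regions of each genotype. A site absent from a list was not called there, which does not show absence of binding. Many sites called for Gli2 only in DKO tumours overlapped H3K27ac regions of both genotypes. Of these 1341 peaks, 47.3% (44.6–50.0%) overlapped H3K27ac regions of SmoM2 tumours and 51.8% (49.2–54.5%) those of DKO tumours. By state, 538 (40.1%) overlapped H3K27ac in both genotypes, 157 (11.7%) in DKO tumours only, 96 (7.16%) in SmoM2 tumours only and 550 (41.0%) in neither. Randomly placed DKO peaks overlapped H3K27ac of DKO tumours in 1.29% of cases on average and at most 2.45%.

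Sites called in both genotypes overlapped H3K27ac more often, but they also ranked higher within the DKO list. The share of DKO peaks in H3K27ac of SmoM2 tumours fell from 72.7% in the highest of the 10 parts to 38.5% in the lowest. In H3K27ac of DKO tumours it fell from 73.4% to 44.8%. The differences that follow were not adjusted for rank, so part of them may reflect it. Of the 85 DKO peaks also in the SmoM2 list, 75.3% (65.2–83.2%) overlapped H3K27ac of SmoM2 tumours, 28.0 percentage points (17.5–36.4, Newcombe interval) above the DKO-only peaks. In H3K27ac of DKO tumours the share was 71.8% (61.4–80.2%), a difference of 19.9 points (9.25–28.8). Of the 63 peaks called only in SmoM2 tumours, 36.5% (25.7–48.9%) overlapped H3K27ac of SmoM2 tumours and 22.2% (13.7–33.9%) that of DKO tumours. Their difference from DKO-only peaks was not tested, and for H3K27ac of SmoM2 tumours the intervals overlap.

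**Figure D2:**
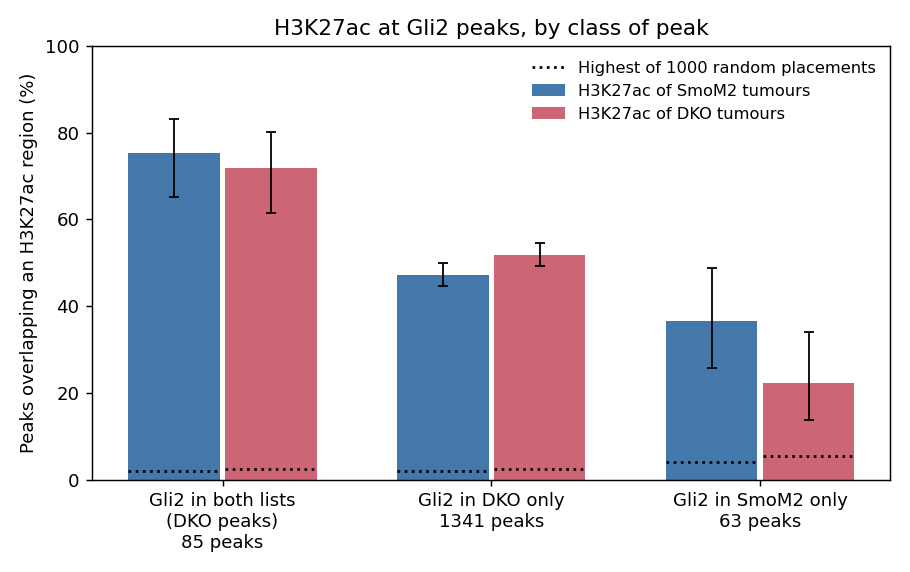
Percentage of Gli2 peaks (vertical axis) that overlap an H3K27ac region of SmoM2 (blue) or DKO tumours (red), for peaks in both lists (85 DKO peaks), in the DKO list only (1341) and in the SmoM2 list only (63), with Wilson 95% intervals as bars. Dotted lines give the highest share among 1000 random placements of all peaks of the Gli2 list that the class belongs to, which is at most 5.41% in each class, below every bar and its interval.

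Gli2 peaks of DKO tumours overlapped H3K36me3 regions less often than randomly placed peaks. These regions covered only 6.22% of the chromosomes in DKO tumours and genes were not analysed, so peaks outside them are not shown to lie outside transcribed genes. In DKO tumours 33 of 1426 peaks (2.31%, 1.65–3.23%) overlapped an H3K36me3 region, less than the mean of 7.39% for random placements (at most 9.89%). In SmoM2 tumours 13 of 148 Gli2 peaks (8.78%, 5.21–14.4%) overlapped H3K36me3, against 6.10% on average and at most 12.8% for random placements, so no difference from random placement was detectable with this number of peaks. The SmoM2 share was 4.76% (3 of 63) among peaks with −log10 q of at least 10, and the DKO share was 4.73% (7 of 148) among the 148 highest DKO peaks. Random placement was not run for these smaller sets, so neither shows a difference from random placement.

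H3K27ac covered more of the genome in DKO tumours. The DKO list held 29504 regions covering 25.2 Mb and the SmoM2 list 21630 regions covering 18.9 Mb, a ratio of 1.36 in number and 1.33 in covered length. Most SmoM2 regions recurred in DKO tumours (73.4%, 72.8–74.0%), and 52.7% (52.2–53.3%) of DKO regions overlapped a SmoM2 region. Random placement gave 1.99% and 1.48% on average. Regions found in only 1 list were narrow and weakly called in both genotypes. Their median −log10 q was 1.99 in DKO tumours against 4.06 for the other DKO regions, and 1.69 in SmoM2 tumours against 2.94. The 13942 DKO-only regions had a median width of 246 bp against 908 bp for the other DKO regions and held 19.7% of the acetylated bases of their list, and the 5749 SmoM2-only regions had 215 bp against 720 bp and held 9.65%.

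The widest acetylated regions were largely the same in both genotypes. After regions at most 10 kb apart were joined, 8 of the 10 widest DKO regions overlapped at least 1 of the 10 widest SmoM2 regions. The widest in DKO tumours lay on chromosome 8 at 122877564–123123350 (246 kb), with 135 kb acetylated in DKO and 84.5 kb in SmoM2 tumours, and it held 10 DKO Gli2 peaks and 1 SmoM2 Gli2 peak. It spanned the SmoM2 regions ranked 7 and 9 by width, which joining left separate in SmoM2 tumours. The region on chromosome 5 at 125486882–125707352 had 100.4 kb acetylated in DKO and 68.4 kb in SmoM2 tumours, with 7 DKO Gli2 peaks and no SmoM2 Gli2 peak. The region on chromosome 7 at 133085648–133238781 had 102.8 kb and 61.2 kb acetylated and contains the second-ranked DKO Gli2 peak. The widest region of SmoM2 tumours, on chromosome 4 at 134107474–134240520 (133 kb), was acetylated over 44.0 kb in SmoM2 and 79.0 kb in DKO tumours. The region on chromosome 9 at 62283255–62399156 was nearly equal (37.9 kb in DKO and 34.1 kb in SmoM2 tumours) and held no Gli2 peak of either genotype.

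**Figure D3:**
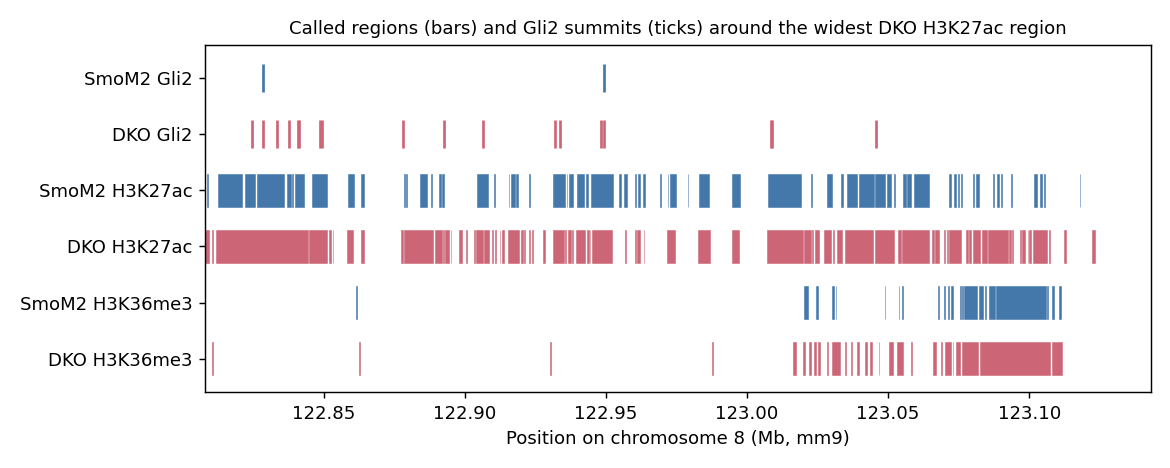
Map of chromosome 8 (horizontal axis, position in Mb, mm9) around the widest joined DKO H3K27ac region, with each row showing 1 list of SmoM2 (blue) or DKO tumours (red), called histone regions as bars and Gli2 summits as vertical ticks. The window holds 18 Gli2 peaks and 75 H3K27ac regions of DKO tumours beside 2 Gli2 peaks and 66 H3K27ac regions of SmoM2 tumours, and H3K36me3 is concentrated at its right end in both.

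The larger acetylated length of the DKO list was spread over most of the genome. Depth was not assessed for the histone lists, so a broad difference of this kind is not shown to be a gain of acetylation. Of 2328 stretches of 1 Mb with H3K27ac in either genotype, 1846 (79.3%) had more acetylated bases in DKO tumours, and the lengths in the 2 genotypes were closely related across stretches (Pearson r = 0.964, across stretches, which are not independent replicates). Stretches were ranked by the difference in kb, not scaled for the list-wide ratio of 1.33, which favours densely marked stretches. The largest differences towards DKO tumours were on chromosome 8 at 125000001–126000000 (83.8 kb in SmoM2 and 139 kb in DKO tumours), chromosome 7 at 133000001–134000000 (87.7 and 142 kb) and chromosome 5 at 125000001–126000000 (102 and 150.0 kb). Chromosome 11 at 120000001–121000000 and chromosome 4 at 134000001–135000000 followed, with differences of 39.5 and 37.3 kb. Acetylated length was higher in SmoM2 tumours on chromosome 13 at 54000001–55000000 (48.5 kb in SmoM2 and 33.8 kb in DKO tumours), on chromosome 6 at 51000001–52000000 (31.2 and 20.8 kb) and on chromosome Y at 2000001–3000000 (11.2 and 0.455 kb).

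As deposited, H3K36me3 regions were fewer but wider in DKO tumours. The DKO list held 67064 regions and the SmoM2 list 89482, a ratio of 0.749, yet these covered 165 Mb in DKO and 138 Mb in SmoM2 tumours, a ratio of 1.19. The median width was 926 bp in DKO and 614 bp in SmoM2 tumours. Most of the marked sequence was common to both, with 118 Mb shared, or 85.1% of the SmoM2 and 71.3% of the DKO bases. After regions at most 1 or 10 kb apart were joined, the number ratio was 0.913 and 0.965 and the covered ratio 1.11 and 1.03, so most of the difference in number disappeared on joining. Among regions with −log10 q of at least 5, which kept only 796 SmoM2 and 2009 DKO regions, the number ratio turned to 2.52 and the covered ratio rose to 3.98, and 24.5% of DKO regions then overlapped a SmoM2 region in place of 68.9%. Among regions with a fold enrichment of at least 3 the number ratio was 0.559, so the direction of the number ratio depended on how regions were filtered.

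By 1 Mb stretches, H3K36me3 covered more bases in DKO tumours in 1838 of 2096 stretches (87.7%, Pearson r = 0.991 across stretches). The largest differences towards DKO tumours, again in kb and not scaled for the list-wide ratio of 1.19, were on chromosome 4 at 97000001–98000000 (115 kb in SmoM2 and 204 kb in DKO tumours), chromosome 7 at 133000001–134000000 (271 and 351 kb) and chromosome 1 at 120000001–121000000 (194 and 273 kb). The chromosome 7 stretch was thus among the 5 largest such differences of both marks. H3K36me3 covered more in SmoM2 tumours on chromosome 12 at 41000001–42000000 (63.8 kb in SmoM2 and 28.3 kb in DKO tumours), chromosome 10 at 5000001–6000000 (101 and 71.8 kb) and chromosome 11 at 118000001–119000000 (144 and 117 kb). The chromosome 11 stretch was also among the 5 with the largest H3K27ac excess in SmoM2 tumours (53.4 and 44.7 kb).

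The length covered by both histone marks differed on the sex chromosomes from that on the autosomes, in a comparison chosen after the values were seen. H3K36me3 regions covered 1.65 times as much of chromosome X in DKO tumours as in SmoM2 tumours, compared with 1.15 to 1.24 times on the 19 autosomes. For H3K27ac the ratio was 1.49 on chromosome X and 1.23 to 1.42 on the autosomes, but the ratio of region numbers on chromosome X (1.37) lay within the autosomal range (1.32–1.42). Chromosome Y held 45 H3K27ac regions in SmoM2 and 3 in DKO tumours, and 7 and 1 H3K36me3 regions. Gli2 peaks on chromosome Y numbered 8 in SmoM2 and 17 in DKO tumours, and on chromosome X 4 and 12. These ratios of 2.13 and 3.00 lay below the autosomal range of 6.35 to 36.

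**Figure D4:**
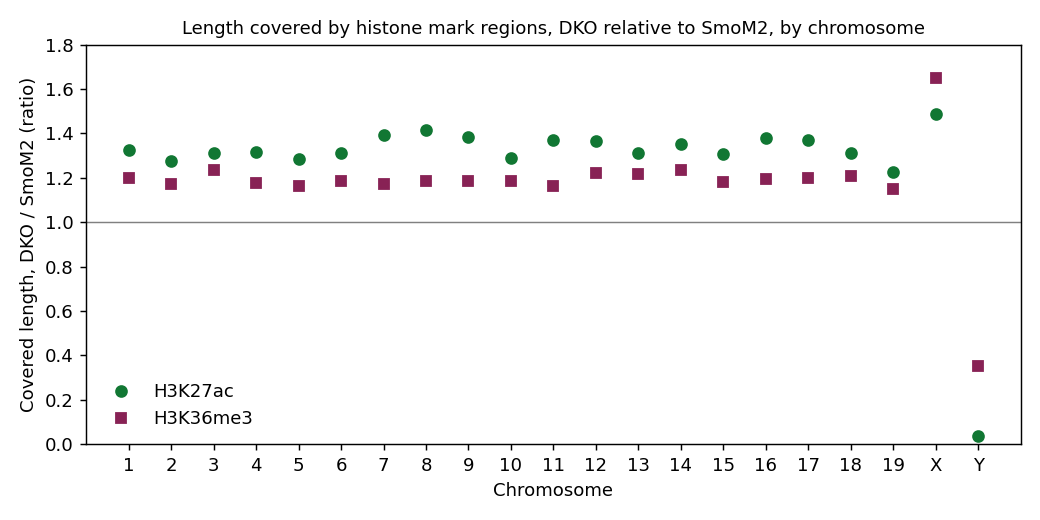
Length covered by H3K27ac (circles) and H3K36me3 regions (squares) in DKO tumours divided by that in SmoM2 tumours (vertical axis, ratio), for each chromosome (horizontal axis). The line marks a ratio of 1. Autosomes lie between 1.15 and 1.42, chromosome X at 1.49 and 1.65, and chromosome Y at 0.0392 and 0.351, from 18.5 and 0.723 kb of H3K27ac and 1.74 and 0.610 kb of H3K36me3 in SmoM2 and DKO tumours.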

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

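A single Gli2 peak of SmoM2 tumours lay outside the chromosomes compared, on the mitochondrial sequence at 15898–16052. Its fold enrichment was 2.12 and its −log10 q 5.08, and it is named here as a signal on a sequence that the reported comparisons leave out. Of the comparisons it enters only the alternative with all sequences, where the ratio of Gli2 peak numbers is 9.57. The DKO list has no peak on that sequence. No biological explanation was tested.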

How the results depend on the processing

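Each alternative changed 1 choice. Of 148 values under settings fixed before the data were examined, 95 stayed within their interval or within 1.5 times the reported value, 52 moved further and 1 reversed, and of 38 added after seeing the data 37 stayed and 1 moved. Some of the values that stayed could not have moved. Only the SmoM2 Gli2 list holds a peak outside the chromosomes compared, so values drawn only from the other lists were fixed under all sequences. The shares of SmoM2 Gli2 peaks in SmoM2 histone regions were likewise fixed when the DKO Gli2 list was shortened. The ratio of Gli2 peak numbers stayed between 9.57 and 15.4, that of H3K27ac covered length between 1.33 and 1.70 and that of H3K36me3 covered length between 1.03 and 3.98. No paired analysis was possible because each list stands for both replicates of a group, although the labels share replicate numbers. Leaving out each replicate was not run for the same reason. Alternatives for genes near Gli2 peaks, gene starts and gene bodies were not run because no mm9 annotation was used. Read numbers are not stated, so depth was assessed only for Gli2, through the background floor, and not for the histone lists. For the values that follow, the cause was not tested unless stated.

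With the DKO Gli2 list reduced to the length of the SmoM2 list, which by construction keeps its strongest peaks, 29.7% of each list overlapped the other. DKO peaks then overlapped H3K27ac of SmoM2 tumours in 73.6% and of DKO tumours in 74.3% of cases, and H3K36me3 of DKO tumours in 4.73%. DKO-only peaks were in H3K27ac in 67.3% of cases for either genotype, and shared DKO peaks in 88.6% (SmoM2) and 90.9% (DKO). At −log10 q of at least 10, 63 SmoM2 peaks remained, the ratio was 15.4, and 4.22% of DKO peaks were in the SmoM2 list. DKO peaks were then in H3K27ac of SmoM2 and DKO tumours in 52.7% and 56.6% of cases, DKO-only peaks in 51.7% and 55.7%, and SmoM2 peaks in H3K36me3 in 4.76%. At a fold of at least 5, 66.1% of SmoM2 Gli2 peaks were in the DKO list. When at least 50% of the peak had to be overlapped, 4.21% of DKO peaks were in the SmoM2 list, 45.0% in H3K27ac of SmoM2 and 48.7% of DKO tumours, and DKO-only peaks in 44.0% and 48.2%. When the summit had to lie in the region, these H3K27ac shares were 45.1%, 49.1%, 43.5% and 48.1%. Random placement within H3K27ac regions raised the chance overlap of Gli2 peaks to 1.76% (SmoM2) and 0.206% (DKO).

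The overlap of H3K27ac regions, as the SmoM2 and then the DKO share, was 90.3% and 51.6% at −log10 q of at least 5, 67.5% and 65.0% in lists of equal length, 63.0% and 38.7% when at least 50% of the region had to be overlapped, 75.1% and 55.9% after joining at 1 kb and 78.7% and 62.3% after joining at 10 kb. For H3K36me3 it was 63.4% and 24.5% at −log10 q of at least 5, 82.9% and 59.2% in lists of equal length, 67.7% and 77.9% at a fold of at least 3, 64.6% and 47.7% when at least 50% of the region had to be overlapped, 70.9% and 68.0% after joining at 1 kb and 77.2% and 78.1% after joining at 10 kb. Without chromosomes X and Y the DKO share was 69.4%. At −log10 q of at least 5 the H3K36me3 number ratio reversed to 2.52, with a covered ratio of 3.98.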

Other observations

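The tests of sequencing depth, of chromatin quality and of high local background, the clusters of Gli2 peaks and the placements within joined regions, were chosen only after the results were seen. The tests of chromatin quality and of chromosome Y were given a more cautious reading once their values were known: by the first bounds, the former explanation had been set aside and the latter accepted.

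Gli2 peaks of DKO tumours were clustered. Of 1426 DKO peaks, 288 (20.2%, 18.2–22.4%) had another within 10 kb, against a mean of 17.4 and at most 42 peaks in 1000 random placements. On autosomes alone 273 of 1397 did (at most 38 placed), and of the 922 of these in joined H3K27ac regions of DKO tumours 236 had another of them within 10 kb, against at most 185 when placed within those regions. Placed peaks also fell in the gaps bridged by joining, whereas 756 of the 929 DKO peaks in joined regions overlapped H3K27ac itself. Chance neighbours are thus understated, and clustering beyond that of the acetylated sequence was not shown. Of 148 SmoM2 peaks 5 had another within 10 kb (mean 0.256, at most 4 placed), and on autosomes 2 of 136 (mean 0.206, at most 4), so clustering of SmoM2 peaks on autosomes was not detectable with this number of peaks. The DKO list had 123 clusters of 2 or more peaks and 6 of 4 or more. The largest held 8 DKO peaks each, on chromosome 8 at 122824534–122849496 (25.0 kb, of which 24.5 kb were acetylated in DKO and 18.8 kb in SmoM2 tumours) and on chromosome 13 at 63654029–63675068 (21.0 kb, with 20.0 and 20.4 kb acetylated). A cluster of 6 on chromosome 11 at 120115917–120125481 was acetylated over 9.57 kb in DKO and 8.39 kb in SmoM2 tumours, and a cluster of 5 on chromosome 4 at 119936218–119962399 over 12.4 and 4.00 kb. Each of these 4 clusters contained 1 peak that was also called in SmoM2 tumours. The other 2 clusters of at least 4 peaks were on chromosome Y.

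The widest 5% of joined DKO H3K27ac regions (897 of 17948) held 437 of the 1426 DKO Gli2 peaks (30.6%, 28.3–33.1%), and 929 peaks lay in any joined region. The 437 were 47.0% (43.8–50.3%) of these 929, little above the 35.0–45.9% of 1000 placements within the joined regions (mean 41.1%). Placed peaks also fell in the bridged gaps, so a preference for wide regions beyond their acetylated sequence was not shown. The widest 5% in SmoM2 tumours held 41 of the 96 SmoM2 Gli2 peaks in joined regions (42.7%, 33.3–52.7%), within the 26.0–57.3% of such placements. H3K27ac regions overlapped H3K36me3 regions of the same genotype in 11.7% of cases in DKO tumours, above the 8.17–9.19% of 100 random placements. In SmoM2 tumours the share was 8.68%, against 7.60–8.50% there. Placement without excluding assembly gaps understates chance overlap, so this small excess in SmoM2 tumours cannot be told from chance.

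The first pattern weighed was the larger number of Gli2 peaks in DKO tumours. Deeper sequencing would raise the floor of the background in the DKO list, taking the floor as the caller's genome-wide background, but it was 0.928 times that of the SmoM2 list (1.30 against 1.40 fragments), and 0.912 times per bp of the narrowest peak. Better chromatin or libraries in DKO tumours for every antibody stays open, since H3K36me3 covered 1.19 times and H3K27ac 1.33 times as much there, both above 1 under every alternative. At −log10 q of at least 5 these covered ratios were 3.98 and 1.70. The ratio of Gli2 peak numbers was 11.2 at that threshold. It counts narrow peaks and is not a covered length, so the lower covered ratios do not weigh against this explanation. A more efficient Gli2 immunoprecipitation stays open too, because at the 85 shared sites the recovered fragments above background, in units of the floor, were 2.80 times higher in DKO tumours (median, bootstrap interval 2.46–3.36, higher at 74 sites), which more Gli2 on DNA also predicts. With 1 list per genotype these cannot be told apart from an effect of the genotype.

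The second pattern was the 63 Gli2 peaks found in SmoM2 tumours only, several of which ranked high without H3K27ac. High local background cannot account for most of them, since 38.1% (24 of 63) lay at over 2 times the floor, although this exceeded the 12.9% (11 of 85) of shared peaks. Stacks of fragments at nearly the same position, as amplification could leave, predict peaks that are narrow for their height. Among peaks with low background the width above the narrowest peak was 0.821 bp per fragment in 36 SmoM2-only peaks and 1.73 bp in 67 shared peaks (permutation p = 0.082), with a median of 19 fragments in both, which leaves this open. Binding specific to SmoM2 tumours was not tested separately and also stays open.

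The third pattern was the contrast of chromosomes X and Y with the autosomes in the length covered by histone marks. A candidate explanation is fewer Y chromosomes in the DKO libraries, that is, more female animals, whose sex the labels do not give. At the 3 chromosome Y Gli2 sites in both lists, the recovered background relative to the floor was 0.450 times as high in DKO as in SmoM2 tumours (0.436–0.531), under the bound of 0.75 set before. A comparison added after this was seen, of 5 autosomal sites with high background, gave a median of 0.796 but a range of 0.381 to 0.995 that includes the chromosome Y values, and for that reason the explanation was left open although the bound was met. The ratio of Gli2 peak numbers on chromosome X, 3.00 from 4 and 12 peaks, lay below the autosomes and is not what more X chromosomes would predict, but rests on few peaks.

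A hypothesis that acetylation was gained where Gli2 was gained was tested against DKO H3K27ac regions of matched width without Gli2. Gli2 peaks called only in DKO tumours stood for gained sites, although a gain of binding was not shown. Of 622 DKO regions with a DKO-only Gli2 peak, 61 (9.81%) had no SmoM2 counterpart, within the 7.88–14.6% of 1000 matched draws (mean 11.1%). In these lists DKO H3K27ac regions with a DKO-only Gli2 peak thus did not lack a SmoM2 counterpart more often than matched regions. Whole regions were scored, so the test does not bear on acetylation at the Gli2 site itself or on its height. At the sites, 157 of the 1341 DKO-only Gli2 peaks (11.7%) overlapped H3K27ac in DKO tumours only and 96 (7.16%) in SmoM2 tumours only. The lists as a whole also held more unshared sequence in DKO tumours, with 14.3 Mb shared of 25.2 Mb in DKO and 18.9 Mb in SmoM2 tumours. The larger count in DKO tumours is therefore no sign of acetylation gained at these sites.

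Another hypothesis was that Gli2 peaks outside H3K27ac regions sit in the gaps between acetylated nucleosomes. Of 670 DKO Gli2 peaks outside DKO H3K27ac regions, 294 (43.9%) lay within 1 kb of such a region, against a mean of 2.09% and at most 4.08% in random placements, and 133 (19.9%) had a region within 1 kb on both sides. Such flanks may therefore account for part of the peaks counted as lacking the mark, but Gli2 peaks also lie near acetylated regions in general, so the position in a gap itself was not shown.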
